A study of Drosophila melanogaster with 4 samples.

How the data were processed

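Drosophila S2 cells were treated with DMSO or with 40 µM radicicol for 15, 30 or 60 min, and polyadenylated RNA was made into Illumina TruSeq libraries, 1 per condition. Per the labels the DMSO cells belong to 0 min. The authors deposited 1 file per library with raw read counts per FlyBase gene, in the unit counts, without normalisation. The submitters' processing notes name Bowtie, HTSeq and the genome build dm3. Versions, options, the strand setting and the annotation release are not given in the sources used here. Each file held 14869 gene IDs and 5 HTSeq entries that name no gene. Gene counts summed to 19153476, 28614983, 30859475 and 31028233 in the DMSO, 15, 30 and 60 min libraries. The entry for reads with several alignments was 0 in each file, and how such reads were handled is not given in the sources used here.

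Symbols, biotypes and exon lengths came from a later annotation than the one used for counting, so no coordinates are printed. Of the IDs, 13524 were paired with a symbol by the gene name table, 8 more by synonyms of the RefSeq annotation, and 1337 had none. An exon length was found for 91.6% of the measured genes. All 4 libraries were analysed in R 4.3.3. Counts were normalised by the TMM method of edgeR 4.0.16 with DMSO as the reference, and counts scaled to a common library size (CPM) use these effective library sizes. Genes with a mean of at least 20 counts over the 4 libraries were measured.

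With 1 library per condition no comparison of a pair of conditions has residual degrees of freedom. Pairs of libraries were therefore compared by a size rule without a p-value: a log2 fold of at least 1 in size with the exact 95% counting interval on that side of 0. The interval is the Clopper-Pearson interval of the share of the pair's counts, scaled by the effective library sizes. Reads without molecular identifiers are not independent molecules, so intervals and lower bounds cover counting error only. Where a library had 0 counts, a bound was computed with 3 counts set for that library. The test fixed for single genes was a straight line on the log scale over minutes through the 4 libraries (edgeR glmQLFit and glmQLFTest, 2 residual degrees of freedom), with Benjamini-Hochberg adjusted p below 0.05 over all measured genes. Slopes are given as log2 change per 60 min. Departures from the line count as error in this test, and radicicol and time cannot be separated between 0 and 15 min. Its p-values measure the scatter of these 4 libraries about a line and no spread between cultures.

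Kinetic classes used the size rule. A gene was early if past it at 15 min, middle if first at 30 min and late if first at 60 min. It was transient if past it at 15 or 30 min and then past it in the opposite direction from that library to the 60 min library.

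There were 26 gene lists fixed before the data were examined: heat shock genes that depend on heat shock factor, constitutive chaperones and Hsp90 co-chaperones, ER stress and unfolded protein response, antioxidant and detoxification genes, metallothioneins, proteasome subunits, autophagy and ubiquitin, immediate-early and JNK-responsive genes, EGFR and Ras/MAPK feedback genes, NF-kB immune genes, JAK/STAT genes, the Enhancer of split complex, ecdysone response genes, FOXO and insulin-response genes, p53 and DNA damage genes, cell cycle genes, Pol II pausing and elongation factors, Polycomb and Trithorax group genes, glycolysis and hypoxia genes, ribosome biogenesis genes, cytosolic ribosomal proteins, mitochondrially encoded transcripts, haemocyte markers, crystal cell and lamellocyte markers, markers of other tissues and reference housekeeping genes. Of their 372 symbols 31 matched no ID of the files. The 25 lists with at least 3 measured members were tested. For each list the median log2 fold was placed among 10000 random lists of the same size matched on mean expression in 10 bins, which describes these libraries only. In medians, members with 0 counts in DMSO stood at their bound. Members past the slope test were counted with p adjusted over all genes and over the list alone. Camera with a preset and with an estimated correlation, and fry, were run on the slope with limma 3.58.1 and edgeR, with p adjusted over the lists. No list passed camera with an estimated correlation. Set tests in the results are camera unless fry is named. Fry asks whether a list's genes move on balance 1 way and compares them with no other genes. It gave adjusted p = 0.0495 for the heat shock list and adjusted p = 0.0597 for the ribosomal proteins. Its lowest adjusted p was 0.0301, for the autophagy and ubiquitin, p53 and DNA damage, and ribosome biogenesis lists. The EGFR list had fry adjusted p = 0.0330, pointing up. Fry adjusted p was 0.0495, pointing up, for the chaperone, ER stress, JNK-responsive, NF-kB, JAK/STAT, ecdysone, FOXO, haemocyte, and crystal cell and lamellocyte lists.

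The genes named were also chosen by a rule fixed before the data were examined: at 60 min the 12 higher and 12 lower genes whose interval lay furthest from 0, at 15 and 30 min 8 and 8, the 10 genes with the smallest p in each direction of the slope test, up to 4 members of each list with the largest fold at 60 min, up to 8 transient genes, each measured Hsp70 copy, Hsp83 and Hsf. Of IDs without a symbol at most 2 per direction are printed. The genes Hsp27, Hsp23 and stv at earlier times and lncRNA:Hsromega are given as further members of the heat shock list, chosen after their values were seen.

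Alternatives fixed before the data were examined were total counts or DESeq2 1.42.0 size factors as normalisation, no count filter or a mean of at least 100 counts, 1.5-fold or 3-fold in place of 2-fold, an interval widened by the dispersion of the slope fit, library sizes without the 50 most abundant genes and the heat shock list, removal of a lowess trend (span 0.3) of the log2 fold on exon length, DESeq2 and limma voom for the slope, time in equal steps or as log2 of minutes plus 15, and leaving out each library. The planned correction for GC content was not run, since no genome sequence was used here. Alternatives chosen after seeing the data were the length correction of the slope test, list medians, named genes and transient genes, protein coding genes only, the 15 min library as the reference, and the listed alternatives for steps and kinetic classes. Pairs of libraries with no true change were simulated 100 times from counting error alone and with the dispersion of the slope fit. Permutation tests used 100000 permutations and were two-sided.

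The methods were tested on simulated data with 7883 genes of which 200 changed. A change of 1, 2 or 3 on the log2 scale at 60 min was recovered by the slope test for 66.5%, 99.5% and 100% of the changed genes, with 7, 5 and 5 other calls, and by the size rule for 45.5%, 100% and 100%, with 22, 30 and 20 other calls. With an added dependence on gene length of 0.5 the slope test made 1833 other calls and the size rule 650, and 13 and 21 after the length correction. This dependence was linear in time and in the log2 of the exon length that the correction fits. Its removal was therefore built in and does not show how well the correction works on the real libraries.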

Results

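Polyadenylated RNA was sequenced from Drosophila melanogaster S2 cells, a line grown from embryonic cells, to follow over time the transcriptional response to inhibition of the chaperone Hsp90. Growing cells received the solvent DMSO or radicicol, a compound that blocks the ATP site of Hsp90, at 40 µM. There were 4 libraries, 1 for each condition: DMSO (labelled 0 min) and radicicol for 15, 30 and 60 min. The gene counts summed to 19153476 in the DMSO library and to 28614983, 30859475 and 31028233 at 15, 30 and 60 min. In the DMSO library 44.1% of the reads were not aligned (95% Clopper-Pearson interval 44.1 to 44.2%), against 18.2% (18.2 to 18.2%), 21.5% (21.5 to 21.5%) and 17.8% (17.8 to 17.8%) in the radicicol libraries. With 1 library per condition no value has a replicate error. Intervals after log2 folds are exact 95% counting intervals, which cover counting error only. Genes are called higher or lower when a radicicol library differed from DMSO by at least 2-fold with the interval on that side of 0, and "rose" and "fell" are kept for genes that passed a test of the slope over the 4 libraries. Of 14869 gene IDs, 7883 had a mean of at least 20 counts and were measured.

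The first comparison, 15 min against DMSO, asks which transcripts responded fastest. Transcripts of the heat-inducible chaperones were already far above their DMSO level. The 6 copies of Hsp70, the main stress-inducible chaperone of the fly, together had 26.8 CPM (counts scaled to a common library size) in DMSO (24.5 to 29.3) and 6834 at 15 min (6805 to 6864), a 255-fold difference (log2 8.0, 7.87 to 8.13). Hsp68, a close relative of Hsp70, had a log2 fold of 5.52 (5.30 to 5.76), and the small heat shock genes Hsp26, Hsp27 and Hsp23 had 3.23 (3.12 to 3.34), 2.63 (2.44 to 2.82) and 1.86 (1.73 to 1.99). Hsp83, the gene of Hsp90 itself, was 2.01-fold higher (log2 1.0, 0.99 to 1.02), and stv, which encodes a co-chaperone of the BAG family, had a log2 fold of 1.84 (1.62 to 2.06).

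Of the 14 measured members of the list of heat shock genes that depend on heat shock factor, 13 were higher at 15 min, and their median log2 fold of 4.38 lay at percentile 100 of 10000 random lists matched on expression. Hsf, the gene of heat shock factor, had a log2 fold of 0.21 (0.09 to 0.32) and was not past the rule. In other lists the genes higher at 15 min were few. They were rho, which encodes a protease that releases ligands of the EGF receptor, with a log2 fold of 1.10 (0.90 to 1.31), the integrin gene ItgaPS4 with 1.13 (0.40 to 1.93), the neuronal gene elav with 1.54 (0.94 to 2.18), and Hsc70-2, which had 1 count in DMSO and a log2 fold of 4.85 (2.30 to 10.18). With the relation of fold to exon length removed, rho (0.96) and ItgaPS4 (0.94) were no longer past the rule at 15 min, while elav (1.07) and Hsc70-2 (4.85) were, and 11 members of the heat shock list were.

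A set of weakly expressed genes was strongly lower in the 15 min library. Frq1, a neuronal calcium sensor gene, had 169 counts in DMSO and 0 at 15 min, which is at least 93.7-fold lower with the 0 set to 3 counts in the library. CG31294, with 105 counts and 0, was at least 58.2-fold lower on the same terms. The end nearest 0 of the exact 95% interval, a weaker bound, was a log2 fold of -6.24 for Frq1 and -5.54 for CG31294. The log2 fold was -5.89 (-7.53 to -4.64) for dpr1, a gene of a neuronal cell surface protein, -5.35 (-6.50 to -4.40) for the transcription factor gene HLH4C, -6.18 (-9.25 to -4.28) for CG3526, -5.22 (-6.37 to -4.26) for the cuticle protein gene TwdlY and -6.00 (-9.07 to -4.10) for CG12078. Atf3, a stress-responsive transcription factor gene, had -2.21 (-2.51 to -1.91). For the 17 protein-coding genes at least 8-fold lower at 15 min, the interval end nearest 0 sets the longest halving time allowed. It went from 2.41 min for Frq1 to 5.98 min for CG10804, if synthesis stopped at the start of treatment. Whether these transcripts decay so fast was not tested. All these folds use the same DMSO library, so a value particular to that library would give the same picture.

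In all, 110 genes were higher and 97 lower at 15 min. With the total counts as library size, which moved the median of all genes by 0.16 on the log2 scale, the split was 192 to 87, and with a library size computed without the 50 most abundant genes and the heat shock list, a shift of 0.11, it was 163 to 89. Among genes annotated as protein coding 45 were lower. Of the 7219 genes with an exon length 84 were higher and 63 lower, and 59 and 57 with the relation of fold to exon length removed.

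At 30 min against DMSO the heat shock genes stood higher still, and some members of the JNK, EGFR and JAK/STAT lists were past the rule. The Hsp70 copies reached 15189 CPM (15146 to 15232), 567-fold over DMSO, and all 14 measured members of the heat shock list were past the rule, with a median log2 fold of 6.26. Hsp26 had 5.42 (5.31 to 5.53), Hsp27 4.95 (4.77 to 5.14), Hsp23 4.38 (4.26 to 4.50), stv 3.43 (3.23 to 3.64) and Hsp83 1.68 (1.67 to 1.70). Genes first higher at 30 min included Ets21C, an ETS transcription factor gene induced by JNK signalling, with 2.45 (2.03 to 2.89), puc, the phosphatase that restrains JNK, with 1.59 (1.5 to 1.68), the matrix protease gene Mmp1 with 1.2 (1.11 to 1.30), and the cell death gene rpr with 1.18 (0.80 to 1.58). The cytokine genes upd2 and upd3, whose products activate JAK/STAT signalling, had 1.75 (0.77 to 2.88) and 1.59 (1.09 to 2.11), and edl, a regulator of ETS factors, had 1.79 (1.64 to 1.94). These were a minority of their lists: 4 of 12 JNK-responsive, 3 of 10 EGFR and 2 of 8 JAK/STAT genes were higher at 30 min (3, 2 and 2 with the length relation removed), and 1 JNK-responsive and 1 EGFR gene were lower.

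On the lower side at 30 min, Frq1 had 1 count (log2 -8.19, -13.50 to -5.69) and CG3526 had 0, about 50-fold or more below its 87 counts in DMSO (interval end log2 -5.31). Most of the other leading genes were IDs that the name tables do not pair with a symbol, such as FBgn0085757 with -6.35 (-6.92 to -5.83) and FBgn0085769 with -6.73 (-7.61 to -5.98). The totals were 265 genes higher and 104 lower, with 50 of the lower ones annotated as protein coding. Of the 7219 genes with an exon length 224 were higher and 67 lower, and 166 and 63 with the length relation removed.

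By 60 min the difference from DMSO covered a far larger part of the transcriptome, with the heat shock genes still at its top. The Hsp70 copies had 18818 CPM (18769 to 18867), 703-fold over DMSO, and the single copies had log2 folds from 9.27 for Hsp70Aa (9.05 to 9.50) and 9.34 for Hsp70Ab (9.10 to 9.58) to 9.40 for Hsp70Bc (8.99 to 9.84), 9.67 for Hsp70Bbb (9.23 to 10.15), 9.82 for Hsp70Bb (9.36 to 10.32) and 9.83 for Hsp70Ba (9.45 to 10.25). These copies are nearly identical in sequence, so their sum is the safer value. Hsp68 had 7.60 (7.37 to 7.83), Hsp26 6.49 (6.39 to 6.60), Hsp27 6.22 (6.04 to 6.4) and Hsp23 5.69 (5.58 to 5.82). Hsp83 was 5.20-fold higher (log2 2.38, 2.37 to 2.39), with 3049 CPM in DMSO and 15846 at 60 min, and its increase had a slope of 2.28 per 60 min (adjusted p = 0.000937, edgeR). Hsf rose by 0.98 per 60 min (adjusted p = 0.000835) without passing 2-fold.

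**Figure D1:**
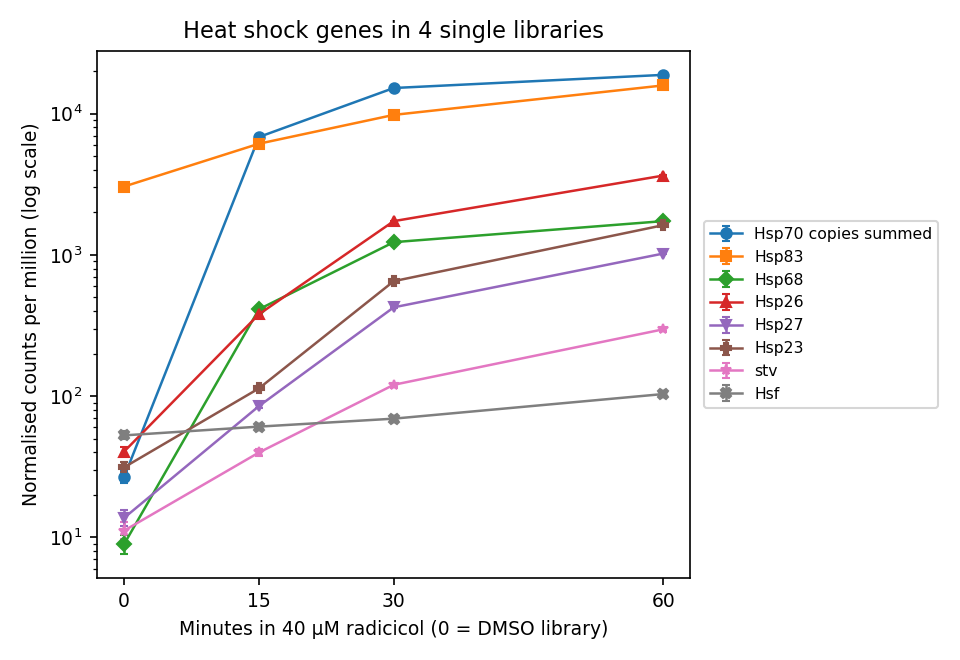
CPM (counts scaled to a common library size, log axis) of the summed Hsp70 copies and 7 single genes against minutes in 40 µM radicicol, with the DMSO library at 0; each point is 1 library and bars are 95% counting intervals. The Hsp70 sum goes from 26.8 to 18818 and Hsp83 from 3049 to 15846, while Hsf goes from 52.7 to 103.

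The measured heat shock list had a median log2 fold of 7.04 at 60 min, again at percentile 100 of the random lists, and all 14 measured members were higher. Of these 14, 6 are the nearly identical Hsp70 copies, which weigh on the median. Not measured were Hsp67Bc, below the count filter, and DnaJ-1, which matched no ID. Hsp22 and CG4456 had 0 counts in each library, and 100% and 90.1% of their exon length overlaps another gene. Hsp67Ba had 0 counts in DMSO, 13 at 30 min and 100 at 60 min, at least 2.51-fold and at least 19.9-fold higher with 3 counts set for DMSO (interval ends log2 0.82 and 3.99). Of its exon length 75.9% overlaps another gene. In the slope test 7 of the 14 rose (7 adjusted over the list alone), among them Hsp23 (5.80 per 60 min, adjusted p = 0.00174), Hsp26 (6.11, adjusted p = 0.00711), Hsp27 (5.98, adjusted p = 0.00293) and stv (4.44, adjusted p = 0.000927). The Hsp70 copies, whose largest step on the log scale came before 15 min, did not follow a straight line and had adjusted p from 0.184 for Hsp70Bc to 0.211 for Hsp70Ab. As a set the list was up by camera with a preset correlation (adjusted p = 0.00373). It did not pass with the estimated correlation of 0.602 (camera adjusted p = 0.784). With the length relation removed the median was 7.42 and 13 members were higher. The exception was the long noncoding RNA gene lncRNA:Hsromega, with 2.91 (2.85 to 2.97) before and 0.69 after.

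The other chaperones that could be measured moved much less. Hsc70-4, Hop, unc-45 and CCT8 of the chaperone list matched no ID of the files, so nothing is known of them here. Of 24 measured constitutive chaperones and Hsp90 co-chaperones 14 rose and 3 fell (the same numbers adjusted over the list alone), and their median log2 fold at 60 min was 0.41, at percentile 89.8. Hsc70-2 had 6.99 (4.50 to 12.30), Hsp110, a nucleotide exchange factor of Hsp70, rose to 1.70 (1.67 to 1.74), Hsc70-1 to 1.53 (0.57 to 2.61) and Hsc70-5, the mitochondrial Hsp70, to 1.06 (1.02 to 1.10). The set test gave adjusted p = 0.186 (adjusted p = 0.790 with an estimated correlation). With the length relation removed 18 rose and 0 fell, and the median of the list was 0.50 at percentile 99.8. Of 17 genes of ER stress and the unfolded protein response 10 rose and 0 fell (10 and 0 adjusted over the list alone), with a median of 0.50 at percentile 92.5. They included PEK, the kinase that phosphorylates eIF2alpha, at 1.95 (1.88 to 2.02), Hsc70-3, the BiP chaperone of the ER, at 1.57 (1.54 to 1.59), Gp93 at 0.96 (0.93 to 0.98) and Cnx99A at 0.95 (0.91 to 0.98). After the length correction PEK (0.98) and Hsc70-3 (0.99) were just short of 2-fold, and the median was 0.33. The set test gave adjusted p = 0.107 (adjusted p = 0.790 with an estimated correlation). Of 15 autophagy and ubiquitin genes 7 rose and 2 fell (7 and 2 adjusted over the list alone), with a median of 0.21 at percentile 76.0. Polyubiquitin Ubi-p63E reached 2.59 (2.56 to 2.63) and the ubiquitin-binding adaptor ref(2)P 1.53 (1.47 to 1.59). Atg17 and Atg1 rose to 1.2 (1.05 to 1.36) and 0.97 (0.81 to 1.14), of which Atg17 had -0.04 with the length relation removed. The test of the set by camera gave adjusted p = 0.507 (adjusted p = 0.784 with an estimated correlation), while fry pointed up with adjusted p = 0.0301. Fry also pointed up for the chaperone and ER stress lists, with adjusted p = 0.0495 for each.

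Signalling targets rose in several lists. Of 12 immediate-early and JNK-responsive genes 9 rose and 0 fell (9 and 0 adjusted over the list alone), with a median of 1.26 at percentile 99.8: Ets21C reached 4.98 (4.58 to 5.41), Mmp1 3.10 (3.01 to 3.19) and puc 3.03 (2.94 to 3.12). Atf3 had -1.75 (-2.03 to -1.49) and no slope (adjusted p = 0.136). The set was up by camera only with the preset correlation (adjusted p = 0.00559, adjusted p = 0.784 with an estimated correlation). With the length relation removed its median was 0.67 at percentile 99.2. Of 10 EGFR and Ras/MAPK feedback genes 8 rose and 0 fell (8 and 0 adjusted over the list alone), with a median of 1.39 at percentile 99.9: rho reached 4.03 (3.85 to 4.21), kek1, an inhibitor of the EGF receptor, 2.67 (2.54 to 2.80), the ETS repressor gene aop 2.62 (2.51 to 2.74) and edl 2.17 (2.02 to 2.32). The set was up by camera only with the preset correlation (adjusted p = 0.00254, adjusted p = 0.784 with an estimated correlation). Its median was 0.38 at percentile 92.7, with 4 of the 10 rising, once the length relation was removed. Of 8 JAK/STAT genes 7 rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 1.12 at percentile 98.4: upd2 reached 3.72 (2.82 to 4.80), upd3 3.47 (3.01 to 3.96), the feedback inhibitor Socs36E 1.64 (1.47 to 1.81) and the kinase gene hop 1.22 (1.06 to 1.39). The set was up by camera only with the preset correlation (adjusted p = 0.00562, adjusted p = 0.784 with an estimated correlation), with a corrected median of 0.59. Its corrected slopes rose for 3 genes and fell for 1, and hop had a corrected fold of 0.22.

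Hormone and metabolic lists held risers too. Of 10 ecdysone response genes 7 rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 1.53 at percentile 99.9: ImpL2, a secreted insulin antagonist, reached 3.10 (3.01 to 3.19), Eip74EF 2.45 (2.08 to 2.85), ftz-f1 2.36 (2.14 to 2.60) and Eip78C 2.27 (1.77 to 2.80). The set was up by camera only with the preset correlation (adjusted p = 0.00662, adjusted p = 0.784 with an estimated correlation), with a corrected median of 0.52. After correction 2 members were higher and 1 lower at 60 min, in place of 7 and 0: ImpL2 had 2.89 and Eip78C 1.09, while Eip74EF (0.88) and ftz-f1 (0.86) were no longer past 2-fold. Of 9 FOXO and insulin-response genes 6 rose and 0 fell (6 and 0 adjusted over the list alone), with a median of 0.72 at percentile 93.3, among them step at 2.45 (2.35 to 2.56), foxo at 1.12 (0.94 to 1.30), srl at 1.09 (1.0 to 1.17) and Thor, which encodes the translation repressor 4E-BP, at 0.89 (0.82 to 0.96). The set was up by camera only with the preset correlation (adjusted p = 0.0328, adjusted p = 0.784 with an estimated correlation), with a corrected median of 0.19. Corrected folds were 1.52 for step and 1.77 for Thor, but 0.37 for foxo and 0.19 for srl, which lost the 2-fold call. Of 13 glycolysis and hypoxia genes 5 rose and 4 fell (5 and 4 adjusted over the list alone), with a median of 0.05 at percentile 48.9. The TOR inhibitors scyl and chrb rose to 2.93 (2.77 to 3.10) and 2.38 (2.13 to 2.64), while the glycolytic genes Gapdh1 and Pglym78 fell to -0.73 (-0.78 to -0.68) and -0.71 (-0.78 to -0.63). Camera gave adjusted p = 0.651 (adjusted p = 0.864 with an estimated correlation).

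Lists with members in both directions were frequent at 60 min. Of 12 immune genes of the NF-kB pathways 3 rose and 2 fell (3 and 2 adjusted over the list alone): the NF-kB factor genes dl and Dif reached 2.28 (2.20 to 2.35) and 1.93 (1.79 to 2.08), and the recognition protein gene PGRP-SD and the antimicrobial peptide gene CecC fell to -2.19 (-3.33 to -1.15) and -1.22 (-1.55 to -0.91). The median was -0.11 at percentile 35.9, whereas camera and fry pointed up (camera adjusted p = 0.723, adjusted p = 0.864 with an estimated correlation), and the corrected median was 0.56. Of 10 p53 and DNA damage genes 5 rose and 2 fell (5 and 2 adjusted over the list alone), with a median of 0.34 at percentile 80.1. Xrp1 reached 2.02 (1.99 to 2.05), Corp 1.60 (1.03 to 2.22), rpr 1.23 (0.85 to 1.63) and tefu 1.18 (1.09 to 1.28), of which tefu had -0.30 with the length relation removed. The set test by camera gave adjusted p = 0.546 (adjusted p = 0.784 with an estimated correlation), while fry pointed up with adjusted p = 0.0301. Of 17 antioxidant and detoxification genes 5 rose and 7 fell (5 and 7 adjusted over the list alone), with a median of -0.14 at percentile 26.8: Gclc, which makes the first step of glutathione synthesis, rose to 2.09 (1.97 to 2.20) and GstD2 to 1.15 (0.81 to 1.5), while haem oxygenase Ho fell to -1.35 (-1.52 to -1.18) and Prx3 to -1.0 (-1.08 to -0.92). The test of the set gave adjusted p = 0.582 (adjusted p = 0.864 with an estimated correlation).

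Of 22 cell cycle genes 5 rose and 8 fell (5 and 8 adjusted over the list alone), with a median of -0.06 at percentile 28.5: E2f1 reached 1.87 (1.79 to 1.95) and CycA 1.2 (1.12 to 1.29), while Cdk1 fell to -1.19 (-1.28 to -1.11) and PCNA to -0.99 (-1.04 to -0.94). Camera gave adjusted p = 0.638 (adjusted p = 0.864 with an estimated correlation). After the length correction E2f1 (0.61), CycA (0.88) and Cdk1 (-0.49) were no longer past 2-fold and PCNA had -0.28, while the slopes of the list rose for 4 genes and fell for 9. Of 14 Pol II pausing and elongation factors 6 rose and 5 fell, 6 and 6 adjusted over the list alone. CycT, the cyclin of P-TEFb, reached 3.04 (2.83 to 3.26), fs(1)h, the fly BET protein, 2.40 (2.29 to 2.51) and Spt6 1.15 (1.05 to 1.25), while Hexim, the inhibitor of P-TEFb, fell to -1.04 (-1.2 to -0.89). Their median was -0.13 at percentile 39.9, camera pointed down and fry up (camera adjusted p = 0.945, adjusted p = 0.949 with an estimated correlation). Of 13 Polycomb and Trithorax group genes 8 rose and 1 fell (8 and 1 adjusted over the list alone), with a median of 0.77 at percentile 98.1: Psc reached 4.21 (4.02 to 4.41), ph-d 2.12 (1.85 to 2.41), trx 1.72 (1.59 to 1.85) and Su(z)12 1.15 (1.0 to 1.28). The set test gave adjusted p = 0.177 (adjusted p = 0.784 with an estimated correlation). With the length relation removed the list's median turned to -0.17, trx to -0.17 and Spt6 to -0.07, while Psc had 2.97. CycT then had 1.80, fs(1)h 0.42 and Hexim -0.65, and the corrected slopes rose for 3 and fell for 4 of the Pol II factors, and rose for 4 and fell for 6 of the Polycomb and Trithorax genes.

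Cytosolic ribosomal protein genes were lower as a group. Of 68 cytosolic ribosomal protein genes 67 fell and 0 rose (67 and 0 adjusted over the list alone), with a median of -1.16 at 60 min, below all 10000 random lists, and 49 were past the rule. Among them RpL17 fell to -1.55 (-1.57 to -1.54), RpL36A to -1.49 (-1.51 to -1.47), RpL18 to -1.45 (-1.47 to -1.43) and RpS28b to -1.42 (-1.44 to -1.40). The 70 ribosomal protein genes found by symbol together took 26.35% of the gene counts in DMSO (26.33 to 26.37%) and 12.95% at 60 min (12.94 to 12.96%). Any among the IDs without a symbol are not included. The set was down by camera with a preset correlation (adjusted p = 1.90e-06). It did not pass with the estimated correlation of 0.916 (camera adjusted p = 0.784). These genes are short, and with the length relation removed the median was -0.36, still below all random lists, 36 fell and 1 was past the rule.

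Of 31 proteasome subunit genes 21 fell and 2 rose (21 and 2 adjusted over the list alone), with a median of -0.56 at percentile 0.115: Prosalpha5 fell to -1.10 (-1.15 to -1.04), Prosalpha3 to -1.07 (-1.12 to -1.02), Prosbeta6 to -0.99 (-1.05 to -0.94) and Prosbeta3 to -0.99 (-1.05 to -0.93). The set was down by camera with a preset correlation (adjusted p = 0.00152). It did not pass with the estimated correlation of 0.673 (camera adjusted p = 0.784). With the length relation removed the median was -0.05, with 6 rising and 7 falling. Of 12 ribosome biogenesis genes 6 fell and 1 rose (6 and 1 adjusted over the list alone), with a median of -0.34 at percentile 7.2. Fib, the methyltransferase of box C/D particles, fell to -1.09 (-1.14 to -1.04), Surf6 to -0.98 (-1.04 to -0.91) and Nop56 to -0.51 (-0.56 to -0.46), and Nopp140 rose to 0.73 (0.67 to 0.79). The test of the set by camera gave adjusted p = 0.152 (adjusted p = 0.784 with an estimated correlation), while fry pointed down with adjusted p = 0.0301. Of 14 mitochondrially encoded transcripts 5 fell and 1 rose (5 and 1 adjusted over the list alone), with a median of -0.08 at percentile 34.3 (camera adjusted p = 0.582, adjusted p = 0.864 with an estimated correlation). mt:srRNA fell to -2.37 (-2.71 to -2.04), mt:ND3 to -1.07 (-1.15 to -0.99) and mt:CoII to -1.06 (-1.08 to -1.03), and mt:ATPase8 rose to 1.49 (0.81 to 2.22). With the length relation removed the median was 0.59 and mt:ND3 had 0.07. MtnA, the 1 metallothionein gene measured, fell to -1.08 (-1.27 to -0.89), and had -0.18 with the length relation removed (slope adjusted p = 0.166).

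Markers of cell identity were also compared. Of 11 haemocyte markers, which S2 cells express, 6 rose and 0 fell (6 and 0 adjusted over the list alone), with a median of 0.50 at percentile 85.8. The cofactor gene ush rose to 1.29 (1.21 to 1.38), hemolectin Hml to 1.14 (1.04 to 1.23), Ppn to 0.78 (0.65 to 0.91) and Pxn to 0.64 (0.63 to 0.66). Camera gave adjusted p = 0.177 (adjusted p = 0.784 with an estimated correlation), and with the length relation removed the median was -0.24, 2 rose and 5 fell, and the named genes had -0.00 (ush), -0.62 (Hml), -0.81 (Ppn) and -0.54 (Pxn). Of 7 crystal cell and lamellocyte markers 4 rose and 0 fell (4 and 0 adjusted over the list alone), with a median of 0.58 at percentile 82.0: peb reached 4.13 (2.54 to 6.44), ItgaPS4 3.0 (2.34 to 3.73) and msn, a kinase gene upstream of JNK, 2.40 (2.33 to 2.48), and ItgaPS5 had 0.58 (-0.29 to 1.52). The set test gave adjusted p = 0.152 (adjusted p = 0.784 with an estimated correlation). Of 3 measured markers of other tissues 2 rose and 0 fell (2 and 0 adjusted over the list alone), with a median of 0.84 at percentile 85.2: elav reached 3.40 (2.86 to 4.01), Act88F 0.84 (0.67 to 1.03), and bam had 0.74 (-0.18 to 1.73). The test of the set gave adjusted p = 0.186 (adjusted p = 0.784 with an estimated correlation). The 3 measured genes of the Enhancer of split complex, targets of Notch, showed no slope (0 rising and 0 falling, also adjusted over the list alone). Their log2 folds were 0.46 (-0.27 to 1.24) for E(spl)mgamma-HLH, 0.41 (0.30 to 0.51) for E(spl)mbeta-HLH and 0.35 (-0.00 to 0.71) for E(spl)m3-HLH, with a median at percentile 67.0 (camera adjusted p = 0.638, adjusted p = 0.864 with an estimated correlation). After the length correction all 3 rose, 2 were higher at 60 min and the median was 1.17 at percentile 96.1, so the call for this list depends on that correction. Of 8 reference housekeeping genes 2 rose and 4 fell (3 and 4 adjusted over the list alone), with a median of -0.14 at percentile 29.8 (camera adjusted p = 0.651, adjusted p = 0.864 with an estimated correlation). Polr2A rose to 1.35 (1.28 to 1.42), while RpL32 fell to -1.33 (-1.35 to -1.32) and Tbp to -1.09 (-1.23 to -0.95). None of these 3 was past 2-fold with the length relation removed (Polr2A 0.052, RpL32 -0.48 and Tbp -0.60).

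**Figure D2:**
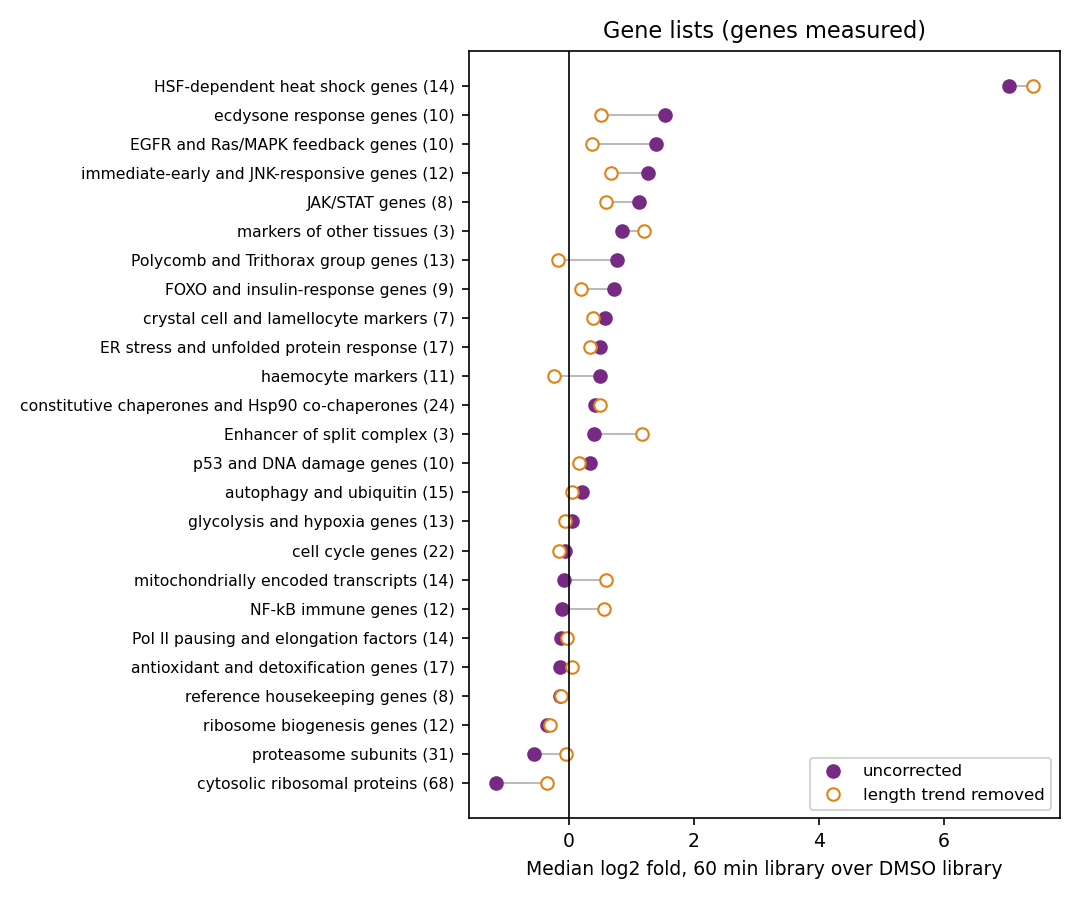
Median log2 fold of the 60 min library over DMSO (horizontal axis) for each of the 25 gene lists with at least 3 measured members, with the number measured in brackets; filled points are uncorrected and open points have the relation to exon length removed. The heat shock list lies at 7.04 and 7.42 and ribosomal proteins at -1.16 and -0.36, while the Polycomb and Trithorax list crosses from 0.77 to -0.17.

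Outside the lists, the genes furthest above DMSO at 60 min included CG30280, with 0 counts in DMSO and 184 at 60 min (at least 36.7-fold higher, interval end log2 4.88), and CG31798, which had 2 counts in DMSO and a log2 fold of 6.89 (5.03 to 9.95). Of the genes with a symbol, those furthest below were HLH4C, with 221 counts in DMSO and 0 at 60 min (at least 123-fold lower), Frq1 (at least 94.2-fold lower), CG31294 (at least 58.5-fold lower; interval ends nearest 0 of -6.63, -6.24 and -5.55 on the log2 scale for these 3), and the rRNA pseudogenes 28SrRNA-Psi:CR40596 with -6.31 (-7.07 to -5.64) and 18SrRNA-Psi:CR41602 with -5.74 (-5.99 to -5.51). Several IDs without a symbol lay as low, FBgn0085757 among them with -6.04. In total 1553 genes were higher and 990 lower at 60 min. Of the 7219 genes with an exon length 1306 were higher and 904 lower. With the length relation removed 673 and 321 of these 7219 passed, of which 512 and 177 also passed without the correction. With the 15 min library in place of DMSO as the reference 1026 were higher and 229 lower.

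**Figure D3:**
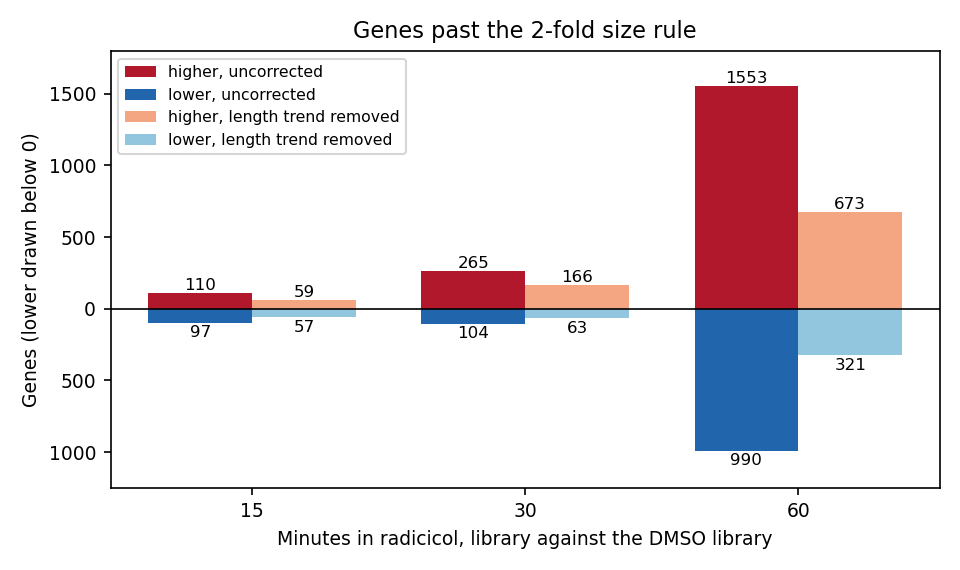
Number of genes past the 2-fold rule against DMSO at 15, 30 and 60 min, higher genes above 0 and lower genes drawn below 0, for all 7883 measured genes and, in pale bars, for the 7219 with an exon length after removal of the length relation. At 60 min 1553 are higher and 990 lower without the correction (1306 and 904 of them with an exon length), and 673 and 321 with it.

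The slope over all 4 libraries, the test fixed for single genes, asked which transcripts moved steadily from DMSO to 60 min. The clearest risers were vri, a transcription factor gene of the circadian clock, with 4.38 per 60 min (adjusted p = 0.000104), and CG32512 with 4.75 (adjusted p = 0.000104). They were followed by Gli, a septate junction gene, with 3.58, ImpL2 with 3.06, the glycogen-targeting gene Gbs-70E with 3.78, the actin regulator gene Vrp1 with 4.06, the zinc finger gene bowl with 3.56, CG6511 with 2.64, Gnpat with 3.15 and FBgn0261548 with 3.93 (adjusted p from 0.000119 to 0.000179). The clearest fallers were GNBP3, a recognition protein for fungi, with -1.47 (adjusted p = 0.000382), CG8064 with -1.51 and HLH4C, followed by CG13625 with -1.31, Ccz1 with -1.56, dwg with -1.39, nSMase with -1.35, dbe with -1.22, CG4338 with -1.40 and ECSIT with -1.45 (adjusted p up to 0.000458). HLH4C had 221, 9, 4 and 0 counts in the DMSO, 15, 30 and 60 min libraries, so its fall came mainly before 15 min. After the length correction each of these genes that has an exon length still passed the slope test (adjusted p up to 0.00127), with smaller slopes for most: 3.50 for vri, 3.07 for Vrp1 and 1.82 for CG6511, and -0.62 for dbe, -0.67 for CG4338 and -0.95 for ECSIT. The 60 min folds of dbe (-0.59), CG4338 (-0.65) and ECSIT (-0.95) were then short of 2-fold. Of the exon length of ImpL2 61.9% and of CG4338 68.4% overlaps another gene. Across genes 2685 rose and 2668 fell, 2530 did not pass, and 5609 had an unadjusted p below 0.05. Of the genes higher at 60 min 1526 rose, and of those lower 958 fell. DESeq2 called 2550 and 2394 (2522 and 2376 shared with edgeR) and limma voom 2686 and 2650 (2656 and 2609 shared). The test has 2 residual degrees of freedom, and it leans on the last library, since without the 60 min library 904 genes rose and 584 fell. It is also open to the length dependence described further on. In simulated data with a dependence on exon length it called 1833 genes beyond the 200 changed ones, and 13 after correction. The simulated dependence grew evenly with time and followed the same exon length that the correction fits, so its removal was built in. The 13 therefore does not carry over to the corrected calls here. With the length relation removed 1956 rose and 1898 fell among 7219 genes, of which 2344 rose and 2490 fell uncorrected. Of the corrected calls 1413 and 1251 were also made without the correction, and 223 genes turned from rising to falling and 69 from falling to rising.

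The steps between consecutive times show when the genes moved. The Hsp70 sum gained 2.22-fold from 15 to 30 min and 1.24-fold from 30 to 60 min, after 255-fold in the first step. In CPM the sum went from 26.8 to 6834, 15189 and 18818, so the larger gain in level came from 15 to 30 min. The small heat shock genes spread their gain more evenly over the first 2 steps: on the log2 scale Hsp26 had 3.23 up to 15 min, 2.19 from 15 to 30 min and 1.07 from 30 to 60 min, Hsp27 had 2.63, 2.32 and 1.27, and Hsp23 had 1.86, 2.52 and 1.32. A few genes of the signalling lists, picked after their values were seen, gained in both of these steps: Ets21C had 1.74 and 2.53, upd2 1.35 and 1.97, rho 1.25 and 1.67, and puc 1.14 and 1.44. Most members of these lists gained little from 15 to 30 min, with median steps of 0.20 for the JNK-responsive, 0.15 for the EGFR and 0.046 for the JAK/STAT list, against 0.78, 0.70 and 0.80 from 30 to 60 min. These steps are not corrected for length, and the median exon lengths of the lists were 4430, 4988 and 4189 nucleotides. All genes with 4000 to 6000 nucleotides of exon had median steps of 0.05 and 0.59, so much of this contrast goes with length. From 15 to 30 min 63 genes were higher and 35 lower, and 8 of the lower ones were annotated as protein coding. From 30 to 60 min 773 were higher and 81 lower, and 600 and 175 with the library size computed without abundant and heat shock genes. Of the genes with an exon length 612 were higher and 79 lower, and 257 and 72 with the length relation removed.

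Classed by the first time past the rule against DMSO, 110 genes were higher early (15 min), 168 in the middle (30 min) and 1282 late (60 min), and 97, 18 and 891 were lower. Of the early higher genes 107 were also past the rule at 60 min, of the middle ones 164, and of the early lower genes 86. All these comparisons share the 1 DMSO library, which alone makes lists overlap. In simulations with no change between libraries an average of 4.81 genes were higher at both 15 and 60 min with the spread of the slope fit, and 2.10 with counting error alone, against the 107 observed. The simulations held no length relation and no value particular to the DMSO library. They therefore do not show that the overlap goes beyond such differences between libraries. No gene passed the rule in opposite directions at 60 min and an earlier time. None was transiently higher. Transiently lower genes, past the rule at 15 or 30 min and then back up by at least 2-fold at 60 min, numbered 11, among them the acetylcholine synthesis gene ChAT (-4.86, -5.33 and -3.06 at 15, 30 and 60 min), CG10804 (-3.03, -3.67 and -1.70), the neuropeptide receptor gene Pdfr (-2.22, -3.27 and -2.18), the polarity gene insc (-2.38, -2.14 and -0.96), the EGF receptor ligand gene vn (-2.13, -2.12 and -1.05), fend (-1.42, -1.57 and 0.94) and Pka-C3 (-1.89, -1.74 and -0.21). The return depends in part on the length relation. Of the 10 with an exon length 5 were still transient with it removed, among them CG10804, fend and Pka-C3, and the step from 30 to 60 min was then 1.84 for ChAT, 0.54 for Pdfr, 0.78 for insc and 0.41 for vn, none of them past the rule.

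Fold and gene length went together in these libraries, which bears on each group above whose members are unusually long or short. Across 7219 genes, which are not independent replicates, the log2 fold over DMSO had a Spearman correlation with exon length of 0.671 at 15 min, 0.618 at 30 min and 0.689 at 60 min. The correlation was 0.166 for the step from 15 to 30 min and 0.701 for the step from 30 to 60 min. At 60 min the 910 genes with 500 to 1000 nucleotides of exon had a median of -0.89 (quartiles -1.14 and -0.53), and the 565 genes above 6000 nucleotides a median of 1.48 (1.05 and 2.11). Of the named list members outside the heat shock list, 54 were higher at 60 min and 33 of them also after the length correction, and 19 were lower and 3 of them also after it. Among those that lost the 2-fold call, the ones without a corrected value so far were Hsc70-5 (0.74), Dif (0.79), ph-d (0.91), Su(z)12 (0.41), Ho (-0.68), CecC (-0.11), Prosalpha5 (-0.32), Prosalpha3 (-0.30), Fib (-0.55), mt:CoII (-0.14), RpL17 (-0.87), RpL36A (-0.49), RpL18 (-0.59) and RpS28b (-0.66). In the lists whose corrected slopes are not given above, the numbers rising and falling with the length relation removed were 9 and 0 for ER stress, 4 and 4 for autophagy and ubiquitin, 7 and 1 for JNK-responsive genes, 6 and 2 for ecdysone response, 4 and 1 for FOXO, 3 and 4 for glycolysis and hypoxia, 5 and 1 for NF-kB genes, 4 and 3 for p53 genes and 6 and 4 for antioxidant genes. They were 1 and 8 for ribosome biogenesis, 8 and 1 for mitochondrially encoded transcripts, 4 and 0 for crystal cell and lamellocyte markers, 2 and 0 for markers of other tissues, 2 and 3 for housekeeping genes, and 6 and 0 for the heat shock list. The median exon length was 901 nucleotides for the ribosomal protein genes and 5514 for the ecdysone list.

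**Figure D4:**
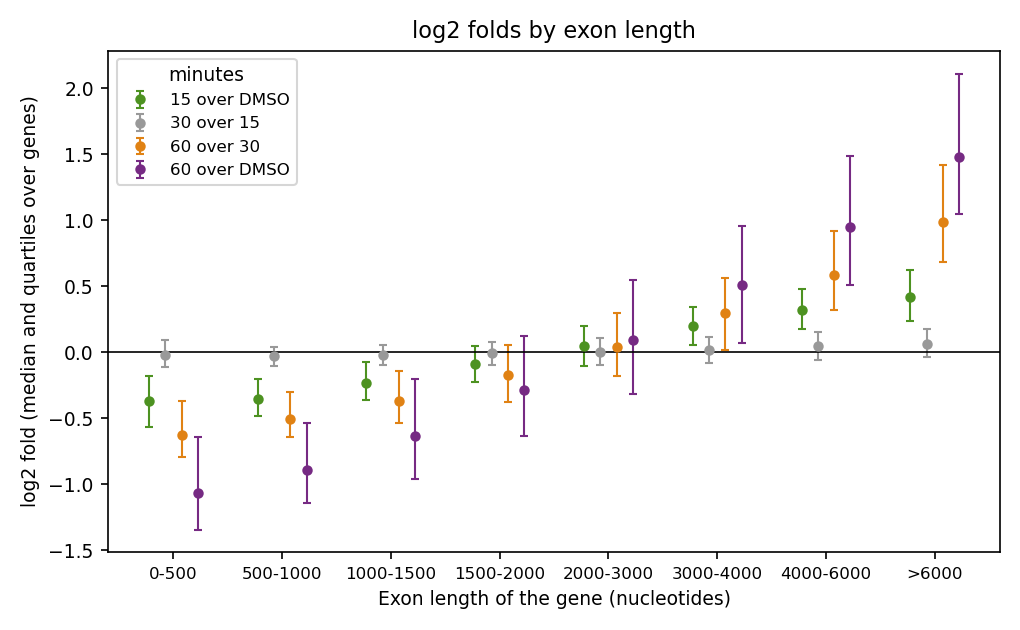
Median log2 fold with quartiles over genes (vertical axis) by exon length in nucleotides (horizontal axis), for 15 min over DMSO, 30 over 15 min, 60 over 30 min and 60 min over DMSO. The 60 min medians go from -0.89 at 500 to 1000 nucleotides to 1.48 above 6000, while those of 30 over 15 min go from -0.03 to 0.07.

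Several classes of RNA without a poly(A) tail took a larger share of the DMSO library than of the radicicol libraries, but tRNA did not at 15 min. The 107 named rRNA genes and rRNA pseudogenes together had log2 folds of -3.89 (-3.99 to -3.79), -5.01 (-5.15 to -4.87) and -5.42 (-5.59 to -5.25) at 15, 30 and 60 min. The 2 genes of 7SL RNA, the RNA of the signal recognition particle, had -3.04 (-3.13 to -2.95), -3.75 (-3.86 to -3.64) and -4.19 (-4.32 to -4.07). The 246 snoRNA and snRNA genes had -1.08 (-1.18 to -0.98), -1.18 (-1.28 to -1.08) and -1.19 (-1.29 to -1.08). The 309 tRNA genes, with 54 counts in DMSO, had -0.10 (-0.61 to 0.42), -0.61 (-1.16 to -0.05) and -0.59 (-1.14 to -0.03). The first 3 classes took 0.0406% (0.0397 to 0.0416%), 0.0326% (0.0318 to 0.0334%) and 0.00944% (0.00901 to 0.00989%) of the gene counts of the DMSO library.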

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

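The tests of the step from 15 to 30 min, of RNAs without a poly(A) tail and of the ratio of gene numbers were chosen only after the results were seen.

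Reads aligned outside annotated features, which the comparisons do not use, took 14.8%, 14.8% and 16.4% of the aligned reads at 15, 30 and 60 min, each above the 14.7% of the DMSO library.

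The dependence of folds on exon length is the pattern that touches most gene groups. A bias of whole libraries, for example from RNA fragmentation or size, predicts the dependence inside a coordinately expressed set, and it was there: across the 68 ribosomal protein genes the Spearman correlation of the 60 min fold with exon length was 0.390 (permutation p = 0.00114). A response that builds up steadily over time is argued against as the whole cause, since the step from 15 to 30 min had a correlation of 0.166 where the steps before and after had 0.671 and 0.701. Unspliced RNA of long genes may add to it and cannot be told apart from such a bias: among 723 protein-coding genes with a single exon the correlation was 0.406, between the bounds of 0.2 and 0.5 set beforehand. A response to radicicol that comes in bursts stays open as well, because each time has 1 library.

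Many more genes were past 2-fold at 60 than at 30 min. The fitted length trend alone does not account for this, since with it removed the number of higher genes at 60 min was still 4.05 times that at 30 min. The fit removes only an average trend on exon lengths of a later annotation. It cannot exclude a length bias that differs from gene to gene. Noise of the 60 min library alone is argued against too: across genes, the corrected folds of 15 min over DMSO and of 60 over 30 min, which share no library, had a Pearson correlation of 0.363 (0.409 without the heat shock list). A spreading late response to radicicol is a candidate explanation. Length bias left after the correction, which could also give such a correlation, stays open. Other biases that differ between libraries, such as GC content, were not tested and stay open.

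Some RNAs without a poly(A) tail were higher in the DMSO library. Of 4 such classes 3 (rRNA and its pseudogenes, 7SL RNA, snoRNA with snRNA) were lower in each radicicol library with intervals below 0, while tRNA was not at 15 min, with a log2 fold of -0.10 (-0.61 to 0.42). This was known before the test was set, so it does not favour less complete poly(A) selection of the DMSO library. That explanation and loss of these RNAs in radicicol cannot be told apart: 7SL RNA had a log2 fold of -3.04 at 15 min already, and with 1 DMSO library condition and library are the same thing. The radicicol libraries also differed from each other, with 7SL RNA at -3.75 and -4.19 and rRNA at -5.01 and -5.42 at 30 and 60 min. A fault of the DMSO library alone would not give these further differences. With 1 library per time they cannot be assigned to time or to library. The DMSO library also had the largest share of reads that were not aligned, 44.1%.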

How the results depend on the processing

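The alternatives for steps and kinetic classes, protein coding genes only, the 15 min library as the reference, and the length correction of slopes, list medians and named genes were chosen only after the results were seen. With DESeq2 size factors, with an interval widened by the dispersion of the slope fit, and for the slope with DESeq2, limma voom, equal steps or the logarithm of time, each gene number stayed within 1.5 times its reported value. No list median and no named gene changed sign with total counts or DESeq2 size factors. Depth leaves a median half-width of 0.14 on the log2 scale for a fold against DMSO.

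With total counts 192 genes were higher at 15 min and 10 first lower at 30 min. With the library size without abundant and heat shock genes 175 were lower from 30 to 60 min and 11 first lower at 30 min. Why these moved was not tested beyond the shift of the median of all genes, 0.16 and 0.11 at 15 min. With no filter, which adds weakly expressed genes, 335 were lower at 15 min, 359 lower at 30 min, 102 higher and 59 lower from 15 to 30 min, and 84 first lower at 30 min. With a mean of at least 100 counts, which tests fewer genes, 72 were higher and 43 lower at 15 min, 48 lower at 30 min, 36 higher from 15 to 30 min, 40 lower from 30 to 60 min, and 6 first lower at 30 min. Both other fold sizes moved the numbers by their construction. With 1.5-fold 459 were higher and 238 lower at 15 min, 826 and 402 at 30 min, 2330 and 2158 at 60 min, 170 and 74 from 15 to 30 min, and 1566 and 857 from 30 to 60 min. Under it 424 were first higher and 216 first lower at 30 min, and 1735 first lower at 60 min. With 3-fold 31 were higher at 15 min, 78 at 30 min, 787 higher and 147 lower at 60 min, 15 and 17 from 15 to 30 min, and 278 and 8 from 30 to 60 min. Under it 53 were first higher and 3 first lower at 30 min, and 703 and 73 at 60 min.

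With protein coding genes only, a smaller set, 45 were lower at 15 min, 50 lower at 30 min and 8 lower from 15 to 30 min. With the 15 min library as the reference 1026 were higher and 229 lower at 60 min, and the cause was not tested. Leaving out 1 library at a time gave 904 to 2686 rising and 584 to 2653 falling genes, the lowest without the 60 min library, whose removal leaves 3 libraries up to 30 min.

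With the length trend removed 59 genes were higher and 57 lower at 15 min, 166 and 63 at 30 min, 673 and 321 at 60 min, 13 lower from 15 to 30 min, 257 higher from 30 to 60 min, 503 first higher and 264 first lower at 60 min. These numbers also leave out genes without an exon length. Uncorrected, the 7219 genes with a length gave 84 and 63 at 15 min, 224 and 67 at 30 min and 1306 and 904 at 60 min. In the same genes 12 were lower from 15 to 30 min and 612 higher from 30 to 60 min. Of the named genes 102 moved outside their counting interval, 7 reversed and 33 stayed inside it. Among genes past the size rule and lists outside the central 95% of random lists, the sign at 60 min reversed for the Polycomb and Trithorax list (-0.17), Atg17 (-0.036), tefu (-0.30), Spt6 (-0.070), trx (-0.17), mt:ND3 (0.069), ush (-0.000449) and Hml (-0.62), whose genes are long apart from the short mt:ND3, so the trend removed was large. The sign also changed for results not called by those rules: haemocyte markers (-0.24), NF-kB genes (0.56), mitochondrially encoded transcripts (0.59), antioxidant genes (0.057), glycolysis and hypoxia genes (-0.061), Ppn (-0.81), Pxn (-0.54) and fend (-0.082). The correction by GC content was not run.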

Other observations

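The look at genes with deep early differences, the subset of mitochondrial genes and the genes named in the next paragraph were chosen only after the results were seen.

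Among 17 protein-coding genes at least 8-fold lower at 15 min, 16 were also at least 8-fold lower at 30 min and 16 at 60 min. They included zld, which encodes the pioneer factor of the early embryonic genome, with 91 counts in DMSO and 7 at 15 min, the acetylcholine receptor gene nAChRalpha6 with 75 and 8, and Lrp4 with 102 and 10. All 3 comparisons share the DMSO library, so a value particular to that library would give the same picture. Simulated libraries with no change gave an average of 0 such genes at 15 min, which speaks to counting noise and the spread of the slope fit but not to such a library. Conversely 11 protein-coding genes were at least 8-fold higher, 8 of them in the heat shock list. The others were Hsc70-2, CG31798 and the NADPH oxidase gene Nox, which had 1 count in DMSO and 20 at 15 min.

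Of the 7 genes of the cytosolic chaperonin in the chaperone list 6 rose, by little: the log2 fold at 60 min went from 0.40 for CCT2 (slope adjusted p = 0.0357), 0.42 for CCT4 (adjusted p = 0.0376) and 0.45 for CCT1 (adjusted p = 0.0203) to 0.63 for CCT6 (adjusted p = 0.00634), 0.66 for CCT3 (adjusted p = 0.00609) and 0.80 for CCT7 (adjusted p = 0.00296). CCT5 had 0.08 (adjusted p = 0.483). They were not a list of their own and were not tested as a set. Of the cell cycle list stg, the Cdc25 phosphatase that starts mitosis, was first lower at 30 min with -1.02 and fell over time (adjusted p = 0.0141). The third NF-kB factor gene, Rel, rose to 1.18 (adjusted p = 0.00106), and the AP-1 genes Jra and kay rose to 1.59 (adjusted p = 0.0005) and 1.63 (adjusted p = 0.000554).

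The dependence on exon length was also looked for in other sets. Across 31 proteasome subunit genes the Spearman correlation was 0.768 (permutation p = 2.00e-05). Across 12 mitochondrially encoded mRNAs it was 0.042 (permutation p = 0.905), and without the 2 short open reading frames that share a transcript with a neighbour, mt:ATPase8 and mt:ND4L, it was 0.806 over 10 (permutation p = 0.00694).

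Whether an arbitrary order of the libraries could give as many slopes was tested by assigning the 4 times to the libraries in all 24 ways. Only 1 order, the real one, gave 5353 genes or more, the highest of the others being 3682 with the 15 and 30 min libraries exchanged. This is the smallest share that 24 orders allow, and it speaks only to an arbitrary order. A difference between libraries that follows the real order for another reason, such as the length relation, would give the same ranking. The test therefore does not show that radicicol caused the slopes.

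A hypothesis that early genes have fewer exons was tested with heat shock genes left out and the length relation removed. The 41 genes higher at 15 min had a mean of 4.15 exons and the 483 first higher at 60 min a mean of 5.41, a difference of -1.26 (two-sided permutation test, p = 0.0612). The groups also differed in median exon length (1525 and 2343 nucleotides) and in median expression (1.61 and 24.7 CPM), either of which can go with exon number. The test did not pass 0.05, and with 41 genes a smaller number of exons in early genes may or may not exist.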
